A study of Mus musculus with 2 samples.

How the data were processed

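Droplet single-cell RNA sequencing (10x Genomics 5′ version) was run on CD45-positive cells sorted from mouse liver tumours, with 1 library from DMSO-treated and 1 from STK-treated MYC-ON mice. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. Per the file headers they were written by Cell Ranger 6.0.2, and per the submitters' processing notes the reads were placed on GRCm38 (mm10). The gene annotation release and the aligner settings are not given in the sources used here. Both matrices list the same 32285 genes, and only barcodes with at least 500 UMIs are present. Tumours were dissociated with a commercial kit and dead cells were excluded by DAPI, per the labels' protocols. The number and the sex of the animals behind each library are not given in the labels. Gene positions were taken from GENCODE vM21, which uses GRCm38, and every gene placed had the same Ensembl identifier in the matrices.

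Cells were kept with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. This left out 632 DMSO and 826 STK barcodes, of which 606 and 805 exceeded the mitochondrial limit. Doublets were called per library with Scrublet (in scanpy 1.11.5) at an expected rate of 8.0%, with score thresholds of 0.262 and 0.256, and 348 DMSO cells (3.12%) and 416 STK cells (3.84%) were removed. The way the Scrublet thresholds were set was revised after the first results had been looked at. The kept cells had median mitochondrial shares of 0.983% and 1.10%, and held 74301041 and 74296862 UMIs.

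Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without integration, on 2000 variable genes that excluded T cell receptor and immunoglobulin segments and ribosomal, mitochondrial and sex-linked genes, with 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2). T and NK clusters were then clustered again among themselves at resolution 1.5. Clusters were named from markers of 28 cell classes, and a name needed a score of at least 1.0 and at least 3 markers at 100 CPM or more. A T or NK sub-cluster needed a score of 0.25 with a lead of 0.1. The markers were fixed before the data were examined, whereas these naming thresholds were set after the clusters had been seen. Clusters with markers of different lineages, or led by genes of another class, were left unnamed.

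For each class of at least 100 cells in both libraries, UMIs were summed per library and divided by all UMIs of the class and scaled to CPM. Cells are not replicates and each group is 1 library, so no test was run and no p-value is given. Shares have exact Clopper-Pearson 95% intervals, CPM values exact Poisson intervals, and ratios of counts exact conditional binomial intervals, all of which cover counting error only. A library with fewer than 3 UMIs of a gene was set to a floor of 3 UMIs in ratios over all cells. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out.

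The comparisons of shares, genes and lists, and the rule for named genes, were written before the data were examined. In Treg-like, CD8 T-like, macrophage-like and monocyte-like cells the 10 highest and the 10 lowest genes by the ratio of CPM were named, and in other classes the 4 highest and the 4 lowest, among genes with at least 50 CPM and 50 UMIs in the library where they were higher. Receptor segment, mitochondrial, ribosomal, sex-linked, erythroid and hepatocyte genes and gene models were left out of this ranking, as were neutrophil granule genes outside neutrophils. Gpr132, Soat1 and Soat2 were named whatever their value, and each described list gave its 2 to 4 members furthest from equal that met the same minimum, leaving out any member whose own value was not used here. Vegfa in NK-like cells met the rule but leads a cluster confined almost wholly to the STK library, and is not reported for that class.

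The 21 gene lists, also fixed beforehand, covered Treg suppressive and effector genes, cholesterol synthesis, LXR targets and sterol efflux, oxysterol enzymes and receptors, cytotoxicity and effector cytokines, exhaustion, naive and memory T cells, T cell receptor early response, type I interferon response, interferon-gamma response and antigen presentation, inflammatory myeloid genes, tumour-associated macrophages, lysosome and lipid handling, neutrophil activation, proliferation, glycolysis and hypoxia, dissociation stress and heat shock, and RNA of hepatocytes or tumour, erythroid cells, neutrophil granules and the sex chromosomes. Members with at least 10 UMIs over both libraries were measured, and lists with fewer than 5 such members gave no median. Each list's median log2 ratio has an interval from 1000 Poisson resamplings of its counts and a percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Members were counted as higher or lower at 1.5 times. A further 2 lists of 9 genes each, of cyclic AMP and of glucocorticoid response genes, were chosen after the named genes had been seen. Genes shifted across classes were those with at least 50 UMIs in at least 10 immune classes and the same shift of at least 1.5 times in at least 80% of the classes measured.

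The sex of single cells was inferred after the data were examined: cells with an Xist UMI and no UMI of Ddx3y, Eif2s3y, Kdm5d or Uty were called female, and cells with a UMI of these and none of Xist male. Within a sex the libraries differed many times in size, so ratios there used counts of 1 or more unchanged. A count of 0 was set to 3 UMIs, and the ratio to equality where that passed it, so such ratios are not lower limits. This replaced the floor within sexes after the first values had been seen. Alternatives planned beforehand were a stricter and a looser cell filter, doublets kept, lower and higher clustering resolution, each library clustered on its own, 15 principal components, Foxp3 UMIs as the definition of Treg cells, other totals and median-of-ratios scaling, equal weight per cell, other count minimums, no thinning, and thinning to 2000 UMIs. Alternatives chosen after seeing the data were female and male cells alone, CD8 T-like cells without the cluster led by naive genes, and classes without cells of at least 20 Jchain UMIs. The latter left out 3 DMSO and 9 STK cells, of which 0 and 4 were Treg-like.

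The ratio and list steps were tested on simulated data, with counts of the real genes drawn from the means of each class and 200 genes changed by 1.5, 2.0 or 4.0 times. Pooled counts were drawn from the Poisson model that the intervals assume. Clumping of a gene's UMIs in a few cells was not simulated, so the coverage does not extend to such genes. For Treg-like cells, over 10703 genes, 96.3% of unchanged genes had an interval that held 0, and the median recovered log2 ratios were 0.56, 0.97 and 2.00. For CD8 T-like cells (11982 genes), macrophage-like cells (12537 genes) and monocyte-like cells (11352 genes) the first share was 95.9%, 95.6% and 96.1%. Intervals held the true ratio of genes changed by 1.5, 2.0 and 4.0 times in 94.0%, 95.5% and 95.5% of cases in Treg-like, 92.5%, 97.0% and 87.9% in CD8 T-like, 95.5%, 92.5% and 93.9% in macrophage-like, and 97.0%, 98.5% and 95.5% in monocyte-like cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.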

Results

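Single-cell RNA sequencing was performed on leukocytes from hepatocellular carcinomas of MYC-ON mice that had been gavaged with DMSO, the vehicle, or with an agent labelled STK, which the labels do not describe further. Tumours were dissociated and live cells carrying CD45, the pan-leukocyte surface antigen, were collected by flow sorting, so every share given here is a share of sorted cells. There were 2 libraries, 1 per group, and both carry the same batch label. The DMSO library held 11784 barcodes and 79322966 UMIs, and the STK library 11672 barcodes and 81859811 UMIs. After filters on depth, mitochondrial RNA and doublets, 10804 DMSO and 10430 STK cells were kept, with medians of 4385.5 and 4788.5 UMIs and 1714 and 1818 genes per cell. With 1 library per group no difference has a replicate check, no test was run, and all intervals cover counting error alone.

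The sexes of the animals contributing to each library were not given in the labels, and transcripts of the sex chromosomes differed between the libraries. Among cells that could be sexed, by Xist, the X-inactivation transcript made in female cells, or by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, 18.9% were female in the DMSO library and 73.7% in the STK library. The female share was 9.52% and 51.5% among Treg-like cells, 14.0% and 66.6% among CD8 T-like cells, and 9.89% and 72.0% among macrophage-like cells. Cells with both kinds of transcript made up 0.824% and 2.03%, and cells with neither 50.6% and 40.7%. Sex mix and treatment could therefore not be separated at the level of libraries, and values within female cells and within male cells are given beside many of the main ones. Female and male cells of a library come from different animals, in numbers not given. Differences between the sexes could therefore not be told apart from differences between animals or their tumours, and values within a sex still compare different animals.

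The first comparison concerned regulatory T cells, the suppressive CD4 lineage defined by the transcription factor Foxp3, because the series addresses Treg function under inhibition of SOAT1, an enzyme that esterifies cholesterol. Treg-like cells made up a smaller part of T cells in the STK library, 405 of 2945 (13.8%, 12.5 to 15.05), than in the DMSO library, 458 of 2421 (18.9%, 17.4 to 20.5), a ratio of 0.727 (0.643 to 0.822). Within each sex the 2 libraries differed little. Male Treg-like cells were 21.6% (19.0 to 24.3) of male T cells in the DMSO library and 20.7% (17.4 to 24.4) in the STK library, a ratio of 0.962 (0.784 to 1.18). Female Treg-like cells were 12.3% (7.87 to 18.0) and 11.7% (9.82 to 13.9) of female T cells, a ratio of 0.955 (0.624 to 1.46). In both libraries the share was higher in male than in female cells. Of all kept cells, Treg-like cells were 4.24% (3.87 to 4.64) and 3.88% (3.52 to 4.27), but 4.91% and 7.06% of male cells, a ratio of 1.44 (1.15 to 1.79), with a ratio of 1.21 (0.769 to 1.89) within female cells. T cells with a Foxp3 UMI after thinning to 1000 UMIs, whatever their cluster, were 7.68% (6.64 to 8.82) and 5.22% (4.44 to 6.09) of T cells.

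**Figure D1:**
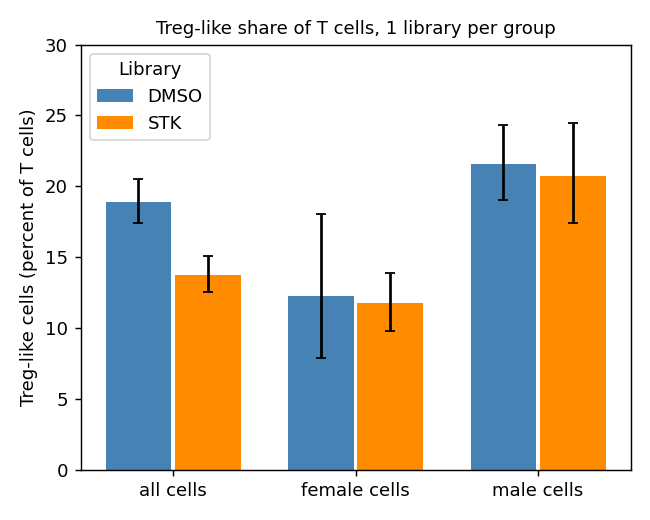
Share of Treg-like cells among T cells (percent) in the DMSO and STK libraries, over all cells and within cells sexed by Xist or Y-linked transcripts; bars are the shares of 1 library each and lines are exact 95% binomial intervals (counting error). The libraries stand at 18.9% and 13.8% over all cells, at 12.3% and 11.7% in female cells, and at 21.6% and 20.7% in male cells.

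The series also concerns GPR132, a G protein-coupled receptor, as the receptor for 20(S)-hydroxycholesterol, an oxysterol. Gpr132 (ENSMUSG00000021298, chromosome 12 from 112850873 to 112868228, minus strand, GRCm38) was higher in the STK library in all 14 immune classes compared, with a median ratio of 2.10 over classes. In Treg-like cells it was at 101 CPM in the DMSO library and 197 CPM in the STK library, a ratio of 1.95 (1.65 to 2.30). Among the T and NK classes the ratio was 2.87 (2.43 to 3.40) in CD4 T-like cells, which reached 419.5 CPM, 2.63 (2.35 to 2.94) in CD8 T-like cells and 3.22 (2.80 to 3.72) in NK-like cells. Macrophage-like cells stood at 54.2 and 110.2 CPM, a ratio of 2.03 (1.81 to 2.28), and monocyte-like cells at 124 and 217 CPM, a ratio of 1.75 (1.58 to 1.93). The smallest ratio was 1.52 (1.27 to 1.82), in cDC1-like cells. Within male cells the Treg-like ratio was 2.20, and within female cells it was 1.09. In Treg-like cells the female DMSO value rested on 11 UMIs, and its interval (log2 −0.76 to 1.16) held equality. In B- or plasma-like cells the ratio was 0.819 within female cells, with 12 and 40 UMIs, and 0.916 within male cells, with 6 and 3 UMIs, and both intervals (log2 −1.25 to 0.78 and −2.75 to 2.10) held equality. By rank, Gpr132 was number 19 of 5118 genes by its median over immune classes.

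The share of cells with a Gpr132 UMI gave the same order after each cell was thinned to 1000 UMIs. Among Treg-like cells, 46 of 445 in the DMSO library (10.3%, 7.67 to 13.5) and 93 of 400 in the STK library (23.3%, 19.2 to 27.7) had a UMI, against 29.9% and 60.7% without thinning. The thinned shares were 7.86% and 18.1% in CD8 T-like cells (25.4% and 48.4% unthinned), 5.75% and 15.6% in NK-like cells (22.9% and 54.2% unthinned), and 5.33% and 9.24% in macrophage-like cells (20.0% and 43.3% unthinned). Hepatocyte or tumour-like cells were taken as a class lacking the receptor, although whether they were sort impurities, cells low in CD45 or doublets with leukocytes was not tested. They gave 0 of 901 cells in the DMSO library, with an upper limit of 0.409%, and 0.985% in the STK library (1.55% and 5.74% unthinned). Median depths were 2877 and 3561 UMIs in Treg-like cells and 28725 and 28983 in hepatocyte or tumour-like cells. Cells left out as too shallow numbered 13 and 5 Treg-like, 11 and 12 CD8 T-like, 7 and 6 NK-like, and 152 and 84 macrophage-like.

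**Figure D2:**
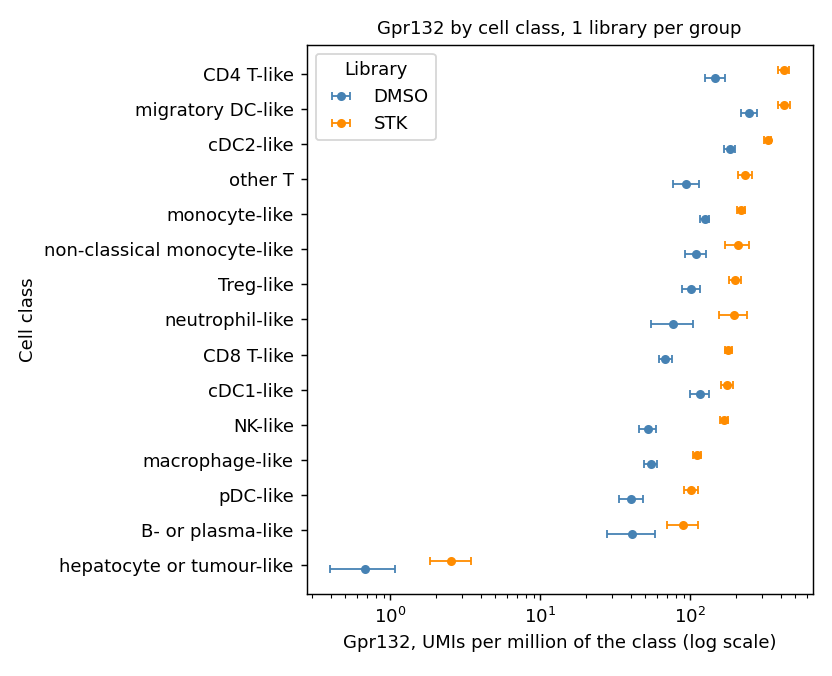
Gpr132 in each cell class, in CPM (UMIs scaled to the total of the class) on a log axis, with 1 point per library and exact 95% Poisson intervals (counting error). All 14 immune classes lie further right in the STK library, with CD4 T-like cells at 146 and 419.5, and hepatocyte or tumour-like cells lie lowest at 0.674 and 2.54.

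Soat1 (ENSMUSG00000026600, chromosome 1 from 156424525 to 156474331, minus strand, GRCm38), the gene of the enzyme named in the series, was close between libraries in most classes. It was at 34.0 and 36.9 CPM in Treg-like cells (ratio 1.09, 0.783 to 1.51), at 122 and 137 CPM in macrophage-like cells (1.12, 1.03 to 1.22) and at 119 and 137 CPM in monocyte-like cells (1.15, 1.03 to 1.28), the last with a ratio of 0.979 within female cells. NK-like cells had 13.4 and 20.4 CPM, a ratio of 1.52 (1.11 to 2.09) that was 0.785 within male cells. Hepatocyte or tumour-like cells had 17.5 and 14.1 CPM, a ratio of 0.806 (0.686 to 0.946), but the ratio was 1.22 within female cells and 1.09 within male cells. Soat2 (ENSMUSG00000023045, chromosome 15 from 102150526 to 102163469, plus strand, GRCm38), the liver and intestinal form of the enzyme, was at 20.5 and 18.6 CPM in hepatocyte or tumour-like cells (0.906, 0.785 to 1.04), while Treg-like cells held 2 and 3 of its UMIs.

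Other leukocyte classes also took different shares of the sorted cells. CD8 T-like cells were 11.2% (10.6 to 11.8) of kept DMSO cells and 15.4% (14.7 to 16.1) of kept STK cells, 1.38 times more, and the ratio was 1.58 within female cells and 1.55 within male cells. NK-like cells were 7.64% (7.14 to 8.15) and 10.7% (10.1 to 11.3), with ratios of 1.54 in female and 1.04 in male cells. Monocyte-like cells, of the Ly6c2 and Ccr2 type, were 1.72 times less frequent in the STK library, 6.77% (6.29 to 7.27) against 11.7% (11.1 to 12.3), with ratios of 0.872 in female and 0.405 in male cells. Non-classical monocyte-like cells, the patrolling type marked by Ace and Treml4, were 2.81 times less frequent, 1.39% (1.17 to 1.63) against 3.91% (3.55 to 4.29). The ratio was 0.181 within female cells, from 72 DMSO and 58 STK cells. Within male cells it was 0.184, from 88 DMSO and only 6 STK cells. Macrophage-like cells were 13.1% (12.4 to 13.7) and 12.9% (12.3 to 13.6) over all cells, but the ratio was 2.18 in female and 1.12 in male cells. All monocyte- or macrophage-like cells together were 28.7% and 21.4%, with ratios of 1.03 within female and 0.742 (0.664 to 0.829) within male cells.

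Neutrophil-like cells were 3.62% and 3.18% of kept cells, CD4 T-like cells 3.98% and 4.41%, pDC-like cells 5.99% and 6.24%, cDC1-like cells 1.31% and 1.74%, cDC2-like cells 3.88% and 3.89%, migratory DC-like cells 1.37% and 1.38%, and B- or plasma-like cells 2.43% and 2.24%. Several of these ratios differed within a sex: cDC1-like cells had 1.93 (1.01 to 3.71) in female and 1.81 (1.30 to 2.52) in male cells, and cDC2-like cells 2.59 (1.61 to 4.16) and 1.18 (0.930 to 1.49). Migratory DC-like cells had 3.15 (1.14 to 8.66) and 0.952, with only 4 female cells in the DMSO library, neutrophil-like cells 0.422 (0.179 to 0.992) and 0.951, and CD4 T-like cells 0.906 and 1.43 (1.10 to 1.88). B- or plasma-like cells had 0.503 (0.352 to 0.719) and 1.07, and 0.483 (0.411 to 0.567) over all cells with each library clustered on its own. T cells in none of the Treg, CD8, CD4 and gamma-delta classes were 2.80% and 4.02%, gamma-delta T-like cells 0.222% and 0.537%, Kupffer cell-like cells 0.0926% and 0.297%, and endothelial-like cells 0.185% and 0.0288% (20 and 3 cells). The endothelial order is not settled, since a cluster of 1 and 68 cells that also scored highest for endothelial markers was left unnamed for too few markers. Nor is the Kupffer order settled. A cluster of 410 and 236 cells counted as macrophage-like was led by Cd5l, a Kupffer cell marker here, and shared leading genes with the Kupffer cell-like cluster. Clusters of 44 and 57 cells with Treg, and of 29 and 65 with neutrophil, as the highest score were left unnamed for markers of 2 lineages. Hepatocyte or tumour-like cells were 8.34% and 5.85% of kept cells in spite of the CD45 sort, with ratios of 0.467 in female and 0.264 in male cells. Cells in clusters without a name, under naming thresholds set after the data were seen, were 14.1% and 15.1%. Boundaries between neighbouring classes moved with the clustering: with each library clustered on its own the CD8 T-like ratio was 2.26 and that of the other T cells 0.199, and with 15 principal components the latter was 0.773.

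Within Treg-like cells, the genes of the suppressive programme stood close to equal between the libraries. The class was named from markers that are members of this same list, Foxp3 and Ctla4 among them. Cells low in these genes could fall outside the class, so the near-equality is partly set by the naming. Il10 and heat shock genes were lower in the STK library, and genes that mark CD8 T cells were higher. Il10 (ENSMUSG00000016529, chromosome 1 from 131019845 to 131024974, plus strand, GRCm38), which encodes an anti-inflammatory cytokine of effector Treg cells, was 2.64 times lower, at 54.6 CPM in the DMSO library and 20.7 CPM in the STK library (114 and 47 UMIs), with 0 and 6 UMIs within female cells and a ratio of 0.693 within male cells, whose log2 interval (−1.37 to 0.26) held equality. Of the 33 measured Treg suppressive and effector genes, 3 were at least 1.5 times higher, 2 at least 1.5 times lower and 28 lay between, with a median log2 ratio of 0.087 (0.053 to 0.20) at percentile 99.8 of random lists, and medians of −0.023 (−0.26 to 0.064) within female and 0.23 (0.15 to 0.33) within male cells. Beside Il10, the members furthest from equal were Areg, a tissue-repair growth factor, at 502 and 881 CPM (1.76 times higher), Nt5e, the ectoenzyme CD73 that makes adenosine (1.67 times higher), and Prdm1, the transcription factor BLIMP-1 (1.52 times lower). Foxp3 (ENSMUSG00000039521, chromosome X from 7573644 to 7595245, plus strand, GRCm38) had a UMI in 36.9% and 32.5% of thinned Treg-like cells (69.9% and 72.8% unthinned) and Ctla4, an inhibitory receptor, in 70.8% and 69.8% (88.0% and 92.6% unthinned). Thinned hepatocyte or tumour-like cells gave 0.111% and 0.164% for Foxp3. The thinned share with an Il10 UMI was 5.17% and 1.25% at 1000 UMIs per cell (11.4% and 8.40% unthinned) and 5.59% and 4.97% at 2000 UMIs per cell. For Soat1 it was 4.72% and 3.50% (12.7% and 17.0% unthinned).

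Genes that also lead the B- or plasma-like cluster came first among the Treg-like genes that were higher in the STK library. Cytotoxic and CD8-lineage genes followed. Jchain, Mzb1 and Slpi had 1, 3 and 5 UMIs in the DMSO library and 5224, 161 and 156 in the STK library. The Jchain UMIs of the STK library lay in 8 cells, and 5 of these held 99.9% of them. Cd7, a T and NK cell surface glycoprotein, was 5.93 times higher, Cd8a and Cd8b1, the chains of the CD8 co-receptor, 5.40 and 3.90 times, the granzyme genes Gzma and Gzmk 4.61 and 3.52 times, Serpinb9, a granzyme B inhibitor, 3.61 times, and Ly6c2, a surface antigen of memory CD8 T cells and monocytes, 3.23 times. Cells with a Cd8a UMI numbered 12 and 44, with 0 and 61 UMIs within female cells and a ratio of 5.92 within male cells. Cd7, Cd8a, Cd8b1 and Gzmk are markers of the CD8 T class here. Whether these UMIs, or those of the list that follows, came from CD8 T cells inside the Treg-like class was not tested. Of 23 measured cytotoxicity and effector cytokine genes, 11 were at least 1.5 times higher, 2 lower and 10 between, with a median log2 ratio of 0.39 (0.29 to 0.57) at percentile 100, and of 0.37 within male cells. Among them Ctsw, a cysteine protease of cytotoxic lymphocytes, was 1.70 times higher and Ccl4, a chemokine, 1.92 times lower.

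The lower genes were led by the inducible HSP70 genes. Hspa1a (ENSMUSG00000091971, chromosome 17 from 34969190 to 34972156, minus strand, GRCm38) was 29.5 times lower, at 130 and 4.40 CPM, and its near-identical neighbour Hspa1b (ENSMUSG00000090877, chromosome 17 from 34956436 to 34959238, minus strand, GRCm38) had 445 and 2 UMIs. Because the coding sequences of this pair are almost the same, the split of reads between them is uncertain. Hsph1, an HSP110 chaperone, was 2.56 times lower, the histone genes Hist1h1d and Hist1h4d 2.61 and 2.43 times, Trim59 2.56 times, Rarg, a retinoic acid receptor, 2.502 times, Tagap 2.41 times, and Zfp36l2, an RNA-decay factor, 2.31 times. Of 21 stress and heat shock genes, 3 were higher, 8 lower and 10 between, with a median of −0.52 (−0.56 to −0.31) at percentile 0 and of −0.34 within female and −0.50 within male cells, and Dnajb1, an HSP40 co-chaperone, was 2.04 times lower.

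Among the metabolic lists, glycolysis and hypoxia genes had 1 of 20 higher, 3 lower and 16 between in Treg-like cells. Their median was −0.40 (−0.45 to −0.29) at percentile 0, or −0.55 within female and −0.25 within male cells. RNA of hepatocytes or tumour, a mark of other cells' RNA, also had a negative median in this class. P4ha1, a collagen prolyl hydroxylase, was 1.87 times lower, Ddit4, an mTORC1 inhibitor, 1.57 times lower, and Slc2a1, the glucose transporter GLUT1, 1.43 times lower. Cholesterol synthesis genes had 3 of 26 higher, 3 lower and 20 between, with a median of 0.021 (−0.15 to 0.20) at percentile 77.0. Ebp, a sterol isomerase, was the only member to meet the naming minimum and was at 114 and 116 CPM. LXR target and sterol efflux genes had 2 of 15 higher, 1 lower and 12 between, with a median of 0.081 (−0.14 to 0.18) at percentile 90.9. Apoe, the lipid carrier, was 1.42 times lower and Smpdl3a, a phosphodiesterase, 1.15 times lower.

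T cell activation lists in Treg-like cells had positive medians over all cells and within male cells, but not within female cells. Exhaustion genes had 6 of 22 higher, 0 lower and 16 between, with a median of 0.22 (0.15 to 0.39), led by Cxcr6, a chemokine receptor of tissue-resident T cells (1.94 times higher), the nuclear receptors Nr4a3 (1.77 times) and Nr4a2 (1.71 times), and Bhlhe40 (1.68 times). The median was 0.39 (0.20 to 0.53) within male cells. Within female cells, of which the DMSO library held 22, 8 of 21 members had fewer than 3 UMIs in a library and no direction could be read. T cell receptor early response genes had 3 of 16 higher, 1 lower and 12 between, with a median of 0.18 (−0.018 to 0.36), and of −0.39 (−0.49 to 0) within female and 0.26 (0.052 to 0.45) within male cells. Naive and memory genes had 3 of 17 higher, 3 lower and 11 between, with a median of 0.25 (−0.043 to 0.36), and of −0.66 (−1.13 to −0.020) within female and 0.48 (0.16 to 0.66) within male cells. Ccr7, the lymph node homing receptor, was 2.87 times higher, at 85.7 and 246 CPM, and Klf2 was 1.37 times lower. Most Treg-like cells came from the same cluster in both libraries (378 and 327 cells). Smaller clusters held 63 and 63 deep cells, with a median of 12450.5 UMIs, and 17 and 15 cells with the heat shock gene Hspb1 among their leading genes.

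In CD8 T-like cells, the cytotoxic lineage of T cells, the 10 highest genes of the STK library included several regulators of transcription, and the 10 lowest included heat shock and chemokine genes. Crem, a cyclic AMP-responsive factor, was 3.62 times higher (3.02 to 4.37), Kdm6b, a histone H3K27 demethylase, 3.60 times, the AP-1 family gene Fosl2 3.45 times, Dgat1, an enzyme of triglyceride synthesis, 3.20 times, Nr4a3 2.97 times, and Egr1, an immediate-early factor, 2.65 times. Vps37b, an ESCRT-I component, went from 281 to 780.3 CPM between the libraries (2.78 times), Gpr132 was 2.63 times higher and Neurl3 2.59 times. Areg was 6.50 times higher, but 5 cells held 84.5% of its UMIs in the DMSO library and 55.1% in the STK library, and it went from 1 to 398 UMIs in female cells, or 2.89 and 129 CPM, with a ratio of 1.34 in male cells.

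Among the lower genes of CD8 T-like cells, Hspa1b and Hspa1a were 14.6 and 8.21 times lower, Hsph1 2.85 times, Dnajb1 1.95 times, and the chemokine genes Ccl3 and Ccl4 4.95 and 2.28 times. The Ccl3 ratio was 0.137 within male cells and 1.94 within female cells. Myc, a growth factor-responsive oncogene, was 2.51 times lower, Txnip, a thioredoxin inhibitor, 2.09 times, and Zfp36, an mRNA-decay factor, 1.90 times. Jchain was 2.02 times lower, with 99.6% and 98.9% of its UMIs in 5 cells, and it went from 1 to 837 UMIs within female cells and from 1415 to 1 within male cells.

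By list, exhaustion genes in CD8 T-like cells had 4 of 22 higher, 0 lower and 18 between, with a median of 0.19 (0.14 to 0.26) at percentile 99.95, and of 1.29 within female and 0.042 within male cells. Nr4a3 led, Tigit, an inhibitory receptor, was 1.55 times higher, Nr4a1 1.45 times, and Pdcd1, which encodes PD-1, 1.41 times, at 287 and 405 CPM. Cytotoxicity genes had 2 of 24 higher, 3 lower and 19 between, with a median of −0.023 (−0.11 to 0.14), where Gzma was 2.24 times higher and Ifng, the interferon-gamma gene, 1.77 times lower. T cell receptor early response genes had 3 of 18 higher, 3 lower and 12 between, with a median of −0.031 at percentile 34.7, and of 0.65 within female and 0.20 (−0.20 to 0.37) within male cells, and Icos, a co-stimulatory receptor, was 2.11 times higher. Naive and memory genes had 2 of 18 higher, 2 lower and 14 between, with a median of −0.21 (−0.27 to −0.091) at percentile 0.12. Ccr7 was 2.15 times higher and Klf2, a quiescence factor, 1.41 times lower. That median was 0.014 within male cells, and 0.11 without the cluster led by naive genes, which held 410 and 414 cells. Cholesterol synthesis genes had 0 of 26 higher, 1 lower and 25 between, with a median of −0.019, and stress genes had 3 of 21 higher, 7 lower and 11 between, with a median of −0.45 (−0.51 to −0.35), which was −0.17 within female and −0.62 within male cells. The other CD8 T-like clusters held 294 and 463 cells, 224 and 252 cycling cells, 150 and 294 cells led by exhaustion genes, and 129 and 182 cells led by interferon-response genes.

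The remaining T and NK classes shared much of this set. In CD4 T-like cells, Ramp3, a receptor activity-modifying protein, was 6.60 times higher, Kdm6b 5.37 times, Areg 5.34 times and Dgat1 4.64 times. Hspa1b, Hspa1a, Ccl4 and Hsph1 were 41.0, 32.1, 5.89 and 5.29 times lower. T cell receptor early response genes in these cells had 7 of 17 higher, 3 lower and 7 between, with a median of 0.34 (0.058 to 0.52). The median was 0.56 (0.028 to 0.91) within female cells and 0.17 (−0.10 to 0.35) within male cells. Nr4a3 was 3.80 times higher, Tnfrsf9, which encodes 4-1BB, 2.54 times, Egr1 2.51 times, and Dusp2, a MAP kinase phosphatase, 2.54 times lower. In NK-like cells Dgat1 was 3.64 times higher, Kdm6b 3.60 times and Crem 3.43 times, while Hspa1a, Hspa1b, Zfp36 and Txnip were 52.3, 32.0, 3.10 and 2.98 times lower. Cytotoxicity genes of NK-like cells had 2 of 23 higher, 5 lower and 16 between, with a median of 0.031 (−0.11 to 0.11). The median was lower within each sex, at −0.17 (−0.24 to −0.0045) in female and −0.17 (−0.31 to −0.044) in male cells. Different clusters held most NK-like cells in each library, one with 59 and 578 cells and another with 478 and 81, so these clusters could not be told apart from the libraries themselves, and genes that lead them are not given. Other T cells came from a cluster of 147 and 306 cells, with Cd160 among its leading genes, and one of 155 and 113 cells led by naive genes. The mix of these clusters differed between the libraries, so it may carry ratios of the class. Rgs16, Gzmc, Dgat1 and Crem were 8.25, 7.35, 6.11 and 3.87 times higher in other T cells. Hspa1a, Hspa1b, Hsph1 and Txnip were 20.4, 13.2, 3.47 and 3.04 times lower there. The Gzmc direction turned under the stricter cell filter, to a log2 ratio of −0.19.

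Macrophage-like cells of the STK library had higher medians for the inflammatory, tumour-associated and lysosomal lists and lower HSP70 genes. The cytotoxicity list, of T and NK cell genes, also had a positive median in this class. Cxcl1, a neutrophil chemoattractant, was 10.99 times higher (8.40 to 14.6), at 7.65 and 84.0 CPM, with a UMI in 17 and 95 cells. Fn1, encoding fibronectin, was 3.91 times higher, Crem 3.47 times, Vegfa, the angiogenic factor, 3.47 times, Slc25a33, a mitochondrial pyrimidine carrier, 3.44 times, Nlrp3, the inflammasome sensor, 3.28 times, and Egr1 3.05 times. Arg1, the arginase of alternatively activated macrophages, was 3.91 times higher over all cells, but went from 1 to 266 UMIs in female cells (log2 interval 1.65 to 9.45) and had a ratio of 0.430 in male cells. Saa3, an acute-phase gene, was 3.40 times higher, with 2 and 690 UMIs in female cells (log2 interval 2.66 to 7.56) and a ratio of 0.242 in male cells. Spp1, encoding osteopontin, was 3.04 times higher, with ratios of 11.8 in female and 1.08 in male cells.

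The lower genes of macrophage-like cells included Hspa1b and Hspa1a, 27.5 and 15.8 times lower, Txnip 2.92 times, Ddit4 2.73 times, Ccl3 2.59 times, Hist1h1e 2.52 times, Aoah, an enzyme that inactivates lipopolysaccharide, 2.30 times, Il16 2.24 times, and Jun, an AP-1 gene, 2.22 times. Retnla (ENSMUSG00000061100, chromosome 16 from 48842551 to 48844461, plus strand, GRCm38), a marker of alternative activation, was 60.9 times lower, but its 585 and 13 UMIs lay in 3 and 5 cells. In cells called male it had 0 and 11 UMIs, 6.69-fold higher with the count of 0 set to 3 UMIs.

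Of 24 tumour-associated macrophage genes, 12 were higher, 3 lower and 9 between, with a median of 0.57 (0.46 to 0.69) at percentile 100 and of 0.22 within male cells. Inflammatory myeloid genes had 8 of 23 higher, 3 lower and 12 between, with a median of 0.50 (0.39 to 0.53) at percentile 100, or 0.95 within female and 0.31 within male cells, and the cytokine genes Il1a and Tnf and the chemokine gene Cxcl2 were 2.86, 1.91 and 1.83 times higher. Lysosome and lipid handling genes had 6 of 22 higher, 0 lower and 16 between, with a median of 0.35 (0.27 to 0.39), or 0.48 within female and 0.16 within male cells. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, was 2.07 times higher, the fatty acid binding protein gene Fabp4 1.85 times, and Ctsl, a cathepsin, and Cd36, a scavenger receptor, 1.66 times each. Type I interferon genes had 0 of 28 higher, 5 lower and 23 between, with a median of −0.29 (−0.34 to −0.20) at percentile 0. That median was closer to 0 within each sex, at −0.054 (−0.21 to 0.11) in female and −0.17 (−0.27 to −0.10) in male cells. Stat2, a signal transducer of that pathway, was 1.86 times lower, Ifi213 1.75 times and Ifit2 1.68 times. Interferon-gamma response and antigen presentation genes had 0 of 28 higher, 2 lower and 26 between, with a median of −0.012, or 0.52 within female and 0.018 within male cells, where Ciita, the MHC class II transactivator, was 1.49 times lower and H2-Aa 1.34 times higher. Cholesterol synthesis genes had 3 of 26 higher, 1 lower and 22 between, with a median of 0.069 at percentile 97.3. All 17 LXR target genes lay within 1.5 times, with a median of 0.012, Abca1, the sterol exporter, 1.40 times higher and Apoe 1.33 times. Stress genes had 2 of 21 higher, 9 lower and 10 between, with a median of −0.44. Most of the class came from a complement-gene cluster in both libraries (1000 and 1114 cells), and 410 and 236 shallow cells, with a median of 1203 UMIs, came from a cluster led by Cd5l.

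Monocyte-like cells, the blood-derived precursors of macrophages, showed higher medians for inflammatory and tumour-associated genes as well. Il1r2, the decoy receptor for interleukin-1, was 4.97 times higher, Spp1 4.63 times, Nr4a3 3.88 times, Slc25a33 3.74 times, Vegfa 3.69 times, Tgm2, a transglutaminase, 3.62 times, Crem 3.49 times and Dgat1 3.12 times. Il1r2 is also among the neutrophil markers used here, and whether its UMIs came from neutrophils was not tested. Trem1, an amplifier of myeloid inflammation, was 3.04 times higher and Mpp7 2.97 times, but the Trem1 ratios were 1.01 in female and 1.40 in male cells and those of Mpp7 1.74 and 1.85. Hspa1b and Hspa1a were 36.5 and 22.1 times lower, the immediate-early genes Jun, Atf3 and Fos 4.24, 3.81 and 2.74 times, Ddit4 4.06 times, Txnip 3.74 times, Dusp6, an ERK phosphatase, 2.94 times, Ccl3 2.81 times and Hist1h2bc 2.78 times.

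Of 23 inflammatory myeloid genes in monocyte-like cells, 12 were higher, 2 lower and 9 between, with a median of 0.60 (0.32 to 0.65) at percentile 100, and Ccl7, a monocyte chemoattractant, was 2.66 times higher, Nlrp3 2.41 times and Cd80, a co-stimulatory ligand, 1.76 times. Neutrophil granule genes, a mark of RNA from another cell type, moved the same way in this class, with 1 of 5 higher, 1 lower and 3 between and a median of 0.50 (0.12 to 0.71) at percentile 99.8, while hepatocyte and tumour genes had a median of −0.49 (−0.59 to −0.23). Tumour-associated macrophage genes had 11 of 21 higher, 2 lower and 8 between, with a median of 0.59 (0.34 to 0.76), Trem2, a lipid receptor of macrophages, 1.52 times higher and Maf 1.66 times lower. Lysosome genes had 3 of 22 higher, 0 lower and 19 between, with a median of 0.25, and Ctsl was 1.55 times higher. Type I interferon genes had 0 of 28 higher, 2 lower and 26 between, with a median of −0.051 over all cells and of 0.31 and 0.41 within female and male cells. Stress genes had 2 of 21 higher, 10 lower and 9 between, with a median of −0.46. The class was formed of a cluster of 917 and 531 cells and a cluster of 342 and 175 cells led by interferon-response genes. In non-classical monocyte-like cells Dgat1, Egr1, Nlrp3 and Thbs1, the thrombospondin gene, were 6.02, 4.91, 4.06 and 3.91 times higher, and Hspa1a, Hspa1b, Ddit4 and Fkbp5, a glucocorticoid-induced chaperone, 36.3, 18.4, 5.03 and 3.89 times lower. Within male cells Fkbp5 had 19 and 1 UMIs, and the interval held equality. All measured neutrophil granule genes, a mark of RNA from another cell type, were also higher in the STK library in non-classical monocyte-like cells.

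A set of genes was shifted the same way across lineages. Of 5118 genes with at least 50 UMIs in at least 10 immune classes, 24 were at least 1.5 times higher and 14 at least 1.5 times lower in at least 80% of the classes where they were measured. By the median over classes, Areg was 7.87 times higher, Crem 3.45 times, Dgat1 3.12 times, Nr4a3 3.11 times, Mpp7 2.97 times, Vps37b 2.56 times and Kdm6b 2.30 times, while Hspa1b was 36.5 times lower, Hspa1a 32.1 times, Hsph1 2.85 times, Ccl3 2.66 times, Jun 2.59 times, Calhm2 2.25 times and Zfp36 1.92 times. Areg fell to median log2 ratios of 1.98 within female and 1.12 within male cells, from 2.98 over all cells, and Nr4a3 (1.75), Dgat1 (1.67) and Crem (1.53) were among the genes above it within male cells. Of these 38 genes, 35 kept a median shift of at least 1.5 times within female cells and within male cells.

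**Figure D3:**
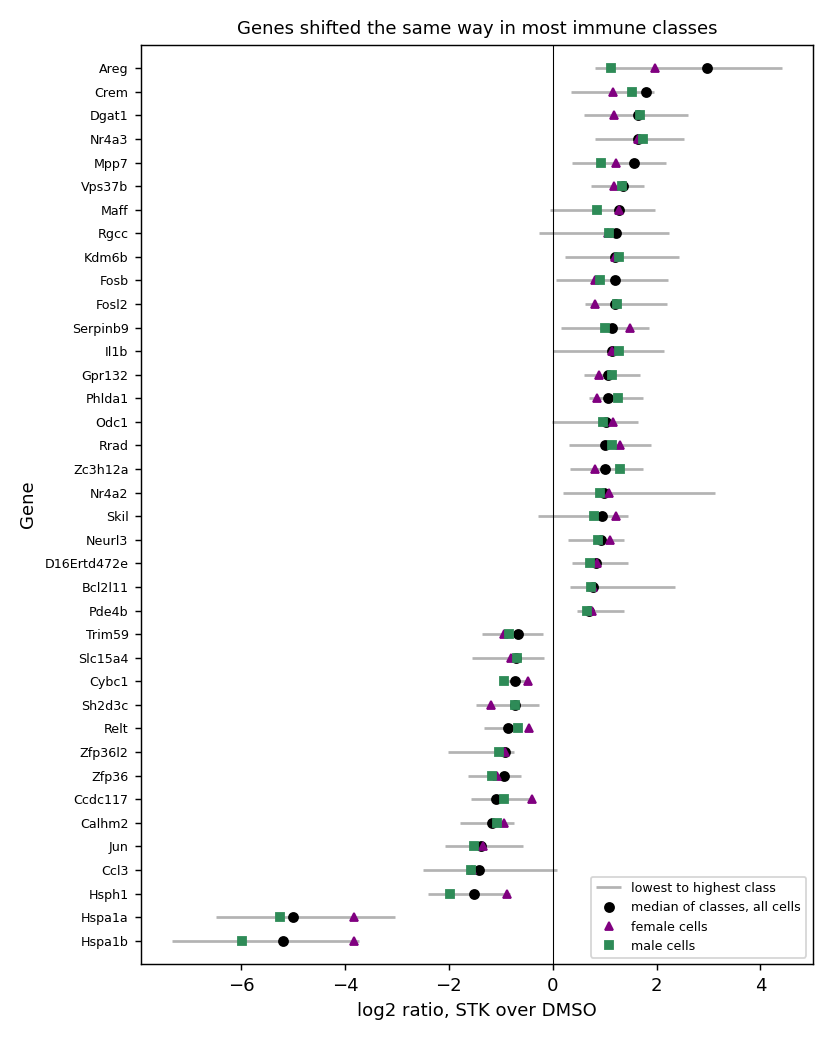
Median log2 ratio (STK over DMSO) over immune classes of the 38 genes shifted by at least 1.5 times in at least 80% of the classes measured; grey lines run from the lowest to the highest class, circles are medians over all cells, and triangles and squares medians within female and within male cells. Over all cells Hspa1a and Hspa1b lie lowest and Areg highest.

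Hepatocyte or tumour-like cells, a class named from non-leukocyte markers whose nature in the sort was not tested, had a higher median for the stress list as a whole. Fosb, Hes1, a Notch target, Atf3 and Ccn1, a YAP target, were 6.56, 5.42, 5.23 and 5.21 times higher in the STK library. Of 21 stress genes, 12 were higher, 2 lower and 7 between, with a median of 1.04 (0.89 to 1.17) at percentile 100, and Egr1, Ier2 and Fos were 3.58, 3.38 and 3.18 times higher. Hspa1a was lower here as in the leukocytes, at 13.7 and 6.09 CPM (2.25 times), and Fosb was also at least 1.5 times higher in 13 of 14 immune classes. Leukocyte lists were higher in these cells too, with medians of 1.10 for T cell receptor early response, 0.91 for inflammatory myeloid, 0.90 for Treg suppressive, 0.87 for cytotoxicity and 0.85 for exhaustion genes, all at percentile 100. Etnk1, Grb10, an adaptor of growth factor receptors, Ppfibp1 and Mrps35 were 2.80, 2.69, 2.62 and 2.55 times lower, but the ratios within male cells were 0.915 for Etnk1, 1.14 for Ppfibp1 and 0.931 for Mrps35. All 26 cholesterol synthesis genes lay within 1.5 times, with a median of −0.090 (−0.12 to −0.028) at percentile 7.12 that was 0.62 within female and −0.32 within male cells. In neutrophil-like cells, Nr4a3, Il1a, Fosb and Vps37b were 5.76, 4.93, 3.42 and 2.76 times higher, and Gdf15, a stress cytokine, Fkbp5, Cxcl3 and Nampt 3.95, 2.83, 2.42 and 2.27 times lower. Few neutrophil-like cells could be sexed, 8 and 15 as female and 54 and 19 as male. Among these, Cxcl3 had 0 and 11 UMIs in female cells, 1.66-fold higher with the count of 0 set to 3 UMIs. Its ratio was 1.18 in male cells. Neutrophil activation genes had 2 of 23 higher, 0 lower and 21 between, with a median of 0.041 (−0.030 to 0.12), Icam1 1.98 times higher and Arg2, a mitochondrial arginase, 1.68 times.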

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

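Each result here was chosen after the data were seen, because its ratio (STK over DMSO) pointed one way in female cells and the other way in male cells, with neither counting interval holding 0 on the log2 scale. The sexes were inferred per cell, there was 1 library per group, and none of these differences between the sexes was tested. The values are log2 ratios, and each difference is the female value less the male value.

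In Treg-like cells, where the DMSO library held 22 female cells, naive and memory genes had medians of −0.66 (−1.13 to −0.020) in female and 0.48 (0.16 to 0.66) in male cells, a difference of −1.14. In female cells 3 of 14 members had fewer than 3 UMIs in a library. A first version set every count under 3 UMIs to 3 within the sexes too, which made genes of these few DMSO cells look high. It gave the suppressive (−0.058), exhaustion (−0.51) and T cell receptor early response lists (−0.46) negative medians in female Treg-like cells with intervals below 0. The handling of low counts within sexes was changed after this was seen, and these 3 lists then had intervals that reached 0. For the exhaustion and T cell receptor early response lists the upper limit was exactly 0. That is the value the changed rule gives to members it sets to equality, so these limits decide no direction.

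In macrophage-like cells the log2 ratio of Arg1 was 4.14 (1.65 to 9.45) in female and −1.22 in male cells, a difference of 5.36, and that of Saa3 was 4.52 (2.66 to 7.56) and −2.04, a difference of 6.56. The female values rested on 1 and 2 UMIs in the DMSO library. Cholesterol synthesis genes in hepatocyte or tumour-like cells had medians of 0.62 and −0.32, a difference of 0.94. Gzma in cDC1-like cells had a UMI in 2 DMSO and 10 STK cells. It had 0 and 60 UMIs in female cells and 10 and 1 UMIs in male cells. The female log2 ratio was 1.11 with the count of 0 set to 3 UMIs, with a lower limit of 0.77. The male log2 ratio was −2.99 (−8.43 to −0.17), a difference of 4.10. Jchain in CD8 T-like cells, nearly all of whose UMIs lay in 5 cells per library, had log2 ratios of 6.56 (4.08 to 11.9) and −9.35 (−14.7 to −6.87), a difference of 15.9, with 1 UMI in a library in each sex.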

How the results depend on the processing

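No paired analysis was possible because there was 1 library per group. The settings for female cells, male cells, CD8 T-like cells without the cluster led by naive genes, and classes without cells of at least 20 Jchain UMIs were chosen after the data were seen, and the others before. Of 159 ratios of class shares under an alternative, 155 kept their direction, or had none to lose because the main interval held equality, and 108 stayed within the main counting interval. Of 369 list medians 364 did so and 304 stayed within, of 1777 ratios of named genes 1758 and 1476, and of 16 ratios of cells with a UMI 16 and 14. The share of Treg-like cells among T cells stayed lower in the STK library under every alternative, with ratios of 0.710 to 0.739 over the planned settings of filter and clustering, 0.679 for Foxp3 UMIs after thinning and 0.721 without Jchain-rich cells, but the intervals within each sex held equality. The settings of the looser filter, the lower resolution and 15 principal components gave no non-classical monocyte-like class, separate clustering gave none in the STK library, and 15 principal components gave no neutrophil-like class. Genes with too few UMIs in a sex, or in classes that lost no Jchain-rich cell, gave no value there. Depth limits values within the sexes: the DMSO library held 22 female Treg-like and 4 female migratory DC-like cells, and the STK library 6 male non-classical monocyte-like cells. In female Treg-like cells, 14 of 17 cholesterol synthesis genes had fewer than 3 UMIs in a library. The way low counts were treated within sexes was changed after the first values were seen. In the values that follow, shares are ratios (STK over DMSO), genes and lists are log2 ratios, those said to be reversed had the opposite direction, and the cause was not tested.

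Female cells alone gave ratios of shares of 0.955 for Treg-like cells among T cells, 1.58 for CD8 T-like, 1.54 for NK-like, 0.872 for monocyte-like, 0.181 for non-classical monocyte-like, 2.18 for macrophage-like and 0.467 for hepatocyte or tumour-like cells. The ratios of other T cells (0.893) and of all monocyte- or macrophage-like cells (1.03) were reversed. Female CD8 T-like cells gave 1.29 for exhaustion, 0.65 for T cell receptor early response, −0.54 for naive and memory, −0.18 for cholesterol synthesis and −0.17 for stress genes, 0.89 for Gpr132, and reversed values of 0.96 for Ccl3 and 6.56 for Jchain. Female CD4 T-like cells gave 0.56 for T cell receptor early response genes. Female Treg-like cells gave a reversed median of −0.023 for suppressive genes. The other lists of female Treg-like cells gave 0 for exhaustion, −0.39 for T cell receptor early response, −0.66 for naive and memory, −0.55 for glycolysis and −0.47 for LXR target genes, and Gpr132 gave 0.12. Female NK-like cells gave −0.17 for cytotoxicity genes and 1.44 for Gpr132. Gpr132 was 1.59 in female cDC2-like and 0.42 in female pDC-like cells, and reversed (−0.29) in female B- or plasma-like cells.

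Female macrophage-like cells gave 0.48 for lysosome, 0.95 for inflammatory, −0.054 for type I interferon, 0.52 for interferon-gamma and −0.21 for stress genes, 1.61 for Gpr132 and 0.51 for Soat1. Female monocyte-like cells gave 0.85 for tumour-associated, 0.46 for lysosome, 0.31 for type I interferon and −0.40 for stress genes, 0.96 for Gpr132, and a reversed −0.031 for Soat1. Female hepatocyte or tumour-like cells gave 1.77 for stress genes, with cholesterol synthesis genes (0.62) and Soat1 (0.29) reversed. Female neutrophil-like cells gave 0.90 for activation genes and a reversed value of at least 0.73 for Cxcl3, with 0 UMIs in the DMSO library.

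Male cells alone gave ratios of shares of 0.962 for Treg-like cells among T cells, 1.55 for CD8 T-like, 1.04 for NK-like, 0.405 for monocyte-like, 0.184 for non-classical monocyte-like, 0.372 for all monocyte-like, 0.742 for all monocyte- or macrophage-like, 1.12 for macrophage-like and 0.264 for hepatocyte or tumour-like cells. Male CD8 T-like cells gave 0.042 for exhaustion and −0.62 for stress genes, with naive and memory genes reversed (0.014). Male Treg-like cells gave 0.23 for suppressive, 0.48 for naive and memory and −0.25 for glycolysis genes. Male NK-like cells gave −0.17 for cytotoxicity genes and a reversed −0.35 for Soat1. Gpr132 was 2.11 in male neutrophil-like and 1.94 in male other T cells. Male macrophage-like cells gave 0.22 for tumour-associated, 0.16 for lysosome, 0.31 for inflammatory, −0.17 for type I interferon, 0.018 for interferon-gamma and −0.61 for stress genes. Arg1 (−1.22), Saa3 (−2.04) and Retnla (2.74, with the 0 UMIs of the DMSO library set to 3) were reversed there. Male monocyte-like cells gave 0.26 for tumour-associated, 0.43 for lysosome, 0.41 for type I interferon and −0.71 for stress genes, and 0.42 for Gpr132. Male hepatocyte or tumour-like cells gave −0.32 for cholesterol synthesis and 0.81 for stress genes and 0.48 for Gpr132, with Soat1 (0.12) and Ppfibp1 (0.18) reversed. Also reversed within male cells were Litaf in B- or plasma-like (−0.59), Gzma in cDC1-like (−2.99), Procr in migratory DC-like (−0.024) and Cxcl3 in neutrophil-like cells (0.23).

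With each library clustered on its own, the ratios of shares were 2.26 for CD8 T-like, 1.27 for NK-like, 0.731 for monocyte-like, 1.13 for macrophage-like and 0.855 for all monocyte- or macrophage-like cells, and other T cells were reversed (0.199). With 15 principal components they were 0.642 for monocyte-like and for all monocyte-like, 1.09 for macrophage-like and 0.848 for all monocyte- or macrophage-like cells, and other T cells were reversed (0.773). The higher resolution gave 1.53 for NK-like and 1.13 for macrophage-like cells, and −0.46 for stress genes in the latter. The lower resolution gave 0.509 for monocyte-like cells. The looser filter gave 1.07 for macrophage-like, 0.568 for all monocyte-like and 0.794 for all monocyte- or macrophage-like cells. The stricter filter gave 0.42 for tumour-associated genes in macrophage-like cells and a reversed −0.19 for Gzmc in other T cells.

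With doublets kept, the share ratio of macrophage-like cells was 1.11. The medians were then 0.29 for cytotoxicity and 0.11 for exhaustion genes in Treg-like cells, 0.86 for stress genes in hepatocyte or tumour-like cells, 0.036 for interferon-gamma genes in macrophage-like cells, −0.14 for type I interferon genes in monocyte-like cells and −0.081 for activation genes in neutrophil-like cells. With the mean of per-cell CPM, exhaustion genes were at 0.29 in CD8 T-like cells, suppressive genes at 0.25 in Treg-like cells, Gpr132 at 0.99 in cDC2-like cells, and type I interferon genes at −0.20 in monocyte-like cells. That setting gave 0.75 for tumour-associated and 0.022 for interferon-gamma genes in macrophage-like cells, and reversed their cholesterol synthesis genes (−0.027). Median-of-ratios scaling gave 0.39 for lysosome, 0.55 for inflammatory and 0.035 for interferon-gamma genes in macrophage-like cells, and totals without background genes gave −0.46 for their stress genes. Without the cluster led by naive genes, CD8 T-like cells gave 0.087 for exhaustion genes and a reversed 0.11 for naive and memory genes. Without Jchain-rich cells, Jchain was reversed in CD8 T-like (0.11) and pDC-like cells (−0.041). Exhaustion genes with at least 50 UMIs gave 0.14 in Treg-like cells. The ratio of shares of Treg-like cells with an Il10 UMI was 0.739 with no thinning and 0.890 with thinning to 2000 UMIs.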

Other observations

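Dendritic and B cells of the STK library had lower HSP70 genes, and their highest genes included Mpp7, Fosl2, Dgat1, Rgcc and Rrad. These were among the genes shifted across classes, a set chosen in part from these same cells, so the overlap is partly built in. In cDC2-like cells, Hilpda, a lipid droplet protein, was 6.09 times higher, Il1r2 5.38 times, Tnfaip2 4.95 times and Mpp7 4.56 times, and Hspa1b, Hspa1a, Ccl3 and Txnip were 57.1, 33.9, 4.44 and 4.02 times lower. In cDC1-like cells, Gzma (with a UMI in 2 and 10 cells), Il1r2, Cd14 and Nkg7 were 8.44, 6.48, 6.03 and 4.21 times higher, and Hspa1b, Hspa1a, Ddit4 and Dnajb1 19.0, 9.42, 7.87 and 5.01 times lower. The Gzma and Nkg7 values may not belong to cDC1-like cells, since lists of T and NK cells were higher there together, with medians of 1.03 (0.53 to 1.34) for cytotoxicity, with 12 of 20 higher, and 0.76 for exhaustion genes. Cytotoxicity genes had medians of 0.31 in macrophage-like and 0.22 in monocyte-like cells. Il1r2, named above in cDC2-like and cDC1-like cells, is also a neutrophil marker here, and the origin of its UMIs was not tested. In migratory DC-like cells, Fosl2, Procr, Dgat1 and Ccl9 were 3.93, 3.32, 2.96 and 2.80 times higher, and Hspa1b, Hspa1a, Ccl3 and Tnf 86.6, 41.6, 5.65 and 5.46 times lower. In pDC-like cells, Rgcc, Gcnt2 and Rnf19b were 3.96, 3.34 and 2.85 times higher, while Jchain went from 5 to 1657 UMIs, the latter in 8 cells. Hspa1b, Hspa1a, Hsph1 and Jun were 111.1, 89.7, 5.23 and 3.53 times lower there. In B- or plasma-like cells, Irs2, Rrad, H1f0 and Litaf were 3.90, 3.70, 3.47 and 3.19 times higher, Prg2 and Gzma 6.48 and 6.28 times lower, and Hspa1b and Hspa1a went from 139 to 1 and from 107 to 3 UMIs.

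Proliferation genes were higher together in some classes, most in migratory DC-like, B- or plasma-like and cDC2-like cells. In migratory DC-like cells 16 of 23 were at least 1.5 times higher, 0 lower and 7 between, with a median log2 ratio of 1.02 (0.62 to 1.30), and Hmgb2, a chromatin protein, was 1.69 times higher. In cDC2-like cells 12 of 24 were higher, 0 lower and 12 between, with a median of 0.59 (0.47 to 0.67), and Ccnb2, Ube2c, Cenpa and Mki67, all of mitosis or the cell cycle, were 2.46, 2.33, 2.16 and 1.89 times higher. That class joined a cluster of 391 and 361 cells with a cluster of 28 and 45 cells whose leading genes included cell cycle genes, so the size of the latter may carry its median. In B- or plasma-like cells 14 of 24 were higher, 0 lower and 10 between, with a median of 0.66 (0.44 to 0.88), and the medians were 0.31 in macrophage-like and 0.19 in NK-like and in cDC1-like cells. In CD4 T-like cells 1 of 23 was higher, 8 lower and 14 between, with a median of −0.36 (−0.63 to −0.11), and the median was −0.14 in Treg-like cells. Oxysterol enzymes and receptors had a median of 0.40 (0.13 to 0.51) in CD8 T-like cells, where 3 of 11 were higher, 1 lower and 7 between and Gpr183, an oxysterol receptor, was 1.33 times higher, and of 0.034 in Treg-like and 0.047 in macrophage-like cells. RNA of hepatocytes or tumour, as a mark of other cells' RNA, had medians of −0.36 in Treg-like, −0.47 in macrophage-like, −0.49 in monocyte-like, −0.63 in cDC2-like and −0.013 in CD8 T-like cells. Neutrophil granule genes had a median of 1.84 in non-classical monocyte-like cells, with all 6 measured members higher, of 0.50 in monocyte-like cells and of −0.091 in neutrophil-like cells. Sex-linked genes had medians of −0.66 in Treg-like and −1.15 in CD8 T-like cells, and erythroid genes had fewer than 5 measured members in each class compared. The larger clusters without a name held 629 and 381, 339 and 343, 266 and 264, and 81 and 217 cells.

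Of the tests that follow, those of the sex mix and of free RNA for Gpr132, of cDC1-like cells alone, of the sex mix for Treg-like cells, of handling, of Hspa1a without its highest cells and of the cyclic AMP list without shifted genes were chosen only after their results were seen, as were the 2 added lists after the named genes. The treatment of low counts within the sexes was also changed after the first values were seen, and the Hspa1a test first left out cells of both libraries, which removed every STK count in several classes.

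The lower share of Treg-like cells among T cells in the STK library may come from the mix of sexes, or of the animals behind them, which could not be told apart. The ratio of shares was 0.962 (0.784 to 1.18) within male cells, an interval that leaves out the 0.727 of all cells, and 0.955 (0.624 to 1.46) within female cells, an interval that does not. Weighting the DMSO shares of the sexes by the STK mix gave 15.5%, beside 14.9% observed among sexed T cells of the STK library and 20.1% in the DMSO library. A treatment effect within a sex stays open inside these intervals.

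For the higher Gpr132, the median log2 ratio over immune classes was 1.14 within male and 0.89 within female cells, against the sex mix, although female Treg-like cells taken alone showed 0.12 with an interval that held 0. The ratio of shares of cells with a UMI was 1.83 after thinning, against depth per cell. Hepatocyte or tumour-like cells of the STK library held 0.0705 UMIs per cell, 13.6% of the excess per cell in the median immune class and, at the upper limit of that count, at most 57.0% in any class, against free RNA as the whole cause, and leukocyte RNA in these cells, which was not excluded, would only raise those shares. Cells with no Hspa1a or Hspa1b UMI had a median of 0.86, so the shift was not confined to cells with a detected UMI of these genes. A cell without such a UMI may still be in a heat shock state, so that state was not excluded as the cause. The log2 ratio fell from 1.02 to 0.58 in macrophage-like, from 0.84 to 0.56 in cDC2-like and from 0.80 to 0.58 in monocyte-like cells. In cDC1-like cells it was 0.36 (−0.099 to 0.86), which decided nothing. In some classes the cells without these UMIs were unlike parts of the DMSO and STK libraries. They were 21.1% and 84.0% of cDC1-like and 36.6% and 84.4% of macrophage-like cells, but 93.6% and 98.8% of neutrophil-like cells. An effect of the treatment and one of handling that differed between the 2 libraries could not be separated with 1 library per group, so an effect of STK on Gpr132 is a hypothesis.

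For the 38 genes shifted across immune classes, the sex mix was not the whole cause, since 92.1% of them kept their shift within both sexes and Hspa1a had medians of −5.26 within male and −3.83 within female cells. Handling of the suspension as a whole and treatment cannot be told apart, because Hspa1a was lower in hepatocyte or tumour-like cells too (−1.17, −1.50 to −0.85), Hspa1b by less (−0.74), while the stress list as a whole was higher there (median 1.04, and 1.77 within female and 0.81 within male cells), and each group has 1 library and the nature of these cells in a CD45 sort was not tested. The 5% of DMSO cells with most Hspa1a UMIs held 57.3% of them in the median class, but without these cells, and with all STK cells kept, the median log2 ratio was still −3.76, against a few cells as the whole cause, except that neutrophil-like cells then held 0 and 1 UMIs and decided nothing. A list of cyclic AMP response genes had a median of 0.50 and lay above 95% of random lists in 10 of 14 classes, but it held Nr4a2 and Pde4b, which are among the shifted genes, and without them it had a median of 0.21 and 5 such classes, all of T or NK cells (0.50 to 0.88), while monocyte-like (−0.44) and cDC1-like cells (−0.34) lay below 95% of random lists, so it did not decide over all classes. Glucocorticoid response genes, likewise chosen after genes were seen, had a median of −0.12 and lay below 95% of random lists in 4 of 14 classes, but above in cDC1-like cells (0.72, −0.15 to 1.00), which did not decide either.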
